A study of Triticum aestivum with 4 samples.

How the data were processed

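Total RNA from roots of wheat (Triticum aestivum) seedlings was labelled with biotin and hybridised to 1-colour Affymetrix wheat arrays. Each of 4 arrays held 1 sample: the cultivars Luohan No.2 and Chinese Spring, each kept in tap water or in a solution of polyethylene glycol (PEG) for 6 h at an osmotic potential of -0.49 MPa. PEG of this size lowers the water potential around the root and is used to imitate drought. Groups were read from the cultivar and treatment labels. With 1 array per group there is no spread between plants, and nothing in the labels says how many seedlings entered a sample.

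The deposited values were intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The 2% trimmed mean of the deposited intensities lay between 99.47 and 99.55 on the 4 arrays, so each array had been scaled to about 100. No detection calls were used here. MAS5 subtracts mismatch signal, which leaves weak probe sets with noisy values near 0, and the single scaling factor per array does not even out differences in the low range. The median signal was 13.5 and 13.9 on the Luohan No.2 water and PEG arrays and 20.3 and 20.2 on the Chinese Spring water and PEG arrays.

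Of 61290 probe sets, 111 controls were set aside, leaving 61179. Signals were floored at their 40th percentile over the 4 arrays, 10.6, and log2 was taken. The share of probe sets above the floor was 54.8% and 55.9% on the Luohan No.2 water and PEG arrays and 64.3% and 64.9% on the Chinese Spring water and PEG arrays. A probe set at the floor on both sides of a comparison was not measured, and one at the floor on 1 side gives a bound, written as at least N-fold. Probe sets at least 2-fold apart were counted in each comparison of 1 array with 1 array, without a test. In comparisons between cultivars, sequence variants that alter hybridisation enter the difference as well. For overlaps, the number that independent lists of those sizes would share is given. Differences between the cultivars' PEG responses were counted at 4-fold.

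The PEG effect with cultivar as a block, and the cultivar effect with condition as a block, were tested in 1 additive fit with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) over the 48877 probe sets above the floor on at least 1 array. This fit has 1 residual degree of freedom per probe set, which holds the difference between the cultivars' responses together with all array noise, and limma's prior added 11.63 degrees of freedom. The p-values therefore set each change mainly against a spread pooled over all tested probe sets, floored ones included, and little against its own. That pooled spread lies between these arrays and may be technical. As a partial measure of probe and array noise, the SD of log2 changes between probe sets of the same sequence cluster was taken. Above the floor on both arrays it was 0.55 for PEG against water in Luohan No.2, 0.50 in Chinese Spring, 0.51 between cultivars in water and 0.58 between cultivars under PEG. Above a signal of 100 on both arrays it was 0.40, 0.27, 0.30 and 0.40 in that order. Such probe sets share the arrays and the RNA, so noise common to a transcript is not in it. Homoeologues or splice forms widen it.

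The limma step was tested on simulated data with 200 changed probe sets, all with mean signals above 100. For the PEG effect with equal noise and no floor, over 48877 probe sets, it recovered 0% of the 2-fold, 65.7% of the 4-fold and 97.0% of the 8-fold changes, with 6 false calls. With noise set by signal level and the floor applied, over 48738 probe sets, it recovered 0% of the 2-fold, 4-fold and 8-fold changes, and the estimated prior was 2.27 degrees of freedom. In that simulation 73 probe sets were called when the prior was allowed to follow signal intensity. The number of calls in this design therefore depends on the estimated prior.

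Genes were named through the platform annotation paired with the probe sets and updated by gene identifier in a RefSeq table of the IWGSC CS RefSeq v2.1 assembly. A single gene was paired with 1273 probe sets, several genes with 0, and 59906 had no gene entry. These made 771 genes, of which 770 were found in the RefSeq table and 102 had a name other than a locus number. Of these 102, 94 were above the floor on at least 1 array. The tables used here give no gene descriptions, so of 33 gene lists fixed before the data were examined, 10 matched any gene, none reached the minimum of 5 measured genes, and the largest held 3. In their place, 7 groups were assembled from gene names after the values had been seen. The median of a group with at least 5 measured members is given with its percentile among 10000 random lists of measured genes matched on mean signal, as a description of these arrays. In simulated lists of 6 genes, 7% of unshifted and 97% of lists shifted by 1 log2 unit lay above the 95th percentile.

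A gene with several probe sets was represented by the brightest. The rule for named genes, fixed before the data were examined, took the 10 largest rises and 10 largest falls with PEG ranked by the smaller of the cultivars' changes, the 5 most positive and 5 most negative differences between responses among genes above the floor on at least 3 arrays, and the 8 genes highest in each cultivar in both conditions. It also took up to 4 members of each reported list, which no list reached. Genes outside the rule are named as such.

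Alternatives were floors at the 20th and 60th percentiles, a pseudocount in place of the floor, quantile normalization, median centring, omission of the 12726 probe sets whose names mark possible cross-hybridisation, a 3-fold threshold, the mean over all probe sets of a gene, and limma without the block, with an intensity trend, and with each array left out. A floor at a signal of 100, the groups of genes and the subsets used for the sizes of shared responses were added after the data were seen. No pair of arrays held copied values. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.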

Results

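Transcript levels were measured in seedling roots of 2 common wheat cultivars, Luohan No.2 and Chinese Spring, after 6 h in PEG or in tap water, with 1 array for each of the 4 combinations. The design asks which transcripts respond to osmotic stress, whether the cultivars share that response, and how they differ with and without stress. Signals above 100, about the level to which each array was scaled, were found for 13345 and 13046 probe sets on the Luohan No.2 water and PEG arrays and for 13719 and 13462 on the Chinese Spring water and PEG arrays. Across probe sets, log2 signals on the water and PEG arrays correlated at r = 0.954 in Luohan No.2 and 0.928 in Chinese Spring. There were no replicate arrays, so folds within 1 cultivar or condition carry no error between plants, and the number of arrays limits their precision.

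Rab15 and LEA1, both late embryogenesis abundant proteins that accumulate in drying seeds and water-stressed tissue, rose with PEG in both cultivars. The Rab15 signal was 17.4 in water and 577.1 in PEG in Luohan No.2, a 33.2-fold difference, and 10.1 and 2736.1 in Chinese Spring, at least 258-fold. LEA1 was 15.8-fold higher in PEG in Luohan No.2 and 69.6-fold higher in Chinese Spring. Over both cultivars, the log2 change was 6.53 ± 0.58 (SE) for Rab15 with an adjusted p of 0.000160 in limma and 5.05 ± 0.51 for LEA1 with an adjusted p of 0.000376. Glc1 rose as well, 4.15-fold in Luohan No.2 and 6.25-fold in Chinese Spring (limma adjusted p = 0.0130), by its brighter probe set, whose name marks possible cross-hybridisation. The other Glc1 probe set was near background, with a log2 difference of at least 0.26 in Luohan No.2 and signals below the floor in Chinese Spring. These calls did not hold in all fits: the limma adjusted p was 0.642 for Rab15, LEA1 and Glc1 with the floor at the 20th percentile and 0.0623, 0.0623 and 0.0920 with the floor at the 60th. With the floor at the 60th percentile the log2 changes in Luohan No.2 and Chinese Spring were at least 4.37 and 6.62 for Rab15. They were 3.98 and 6.12 for LEA1 and 2.05 and 2.64 for Glc1. Over all alternative floors, scalings and probe set filters the adjusted p ranged from 1.96e-17 to 0.642 for Rab15, from 8.57e-14 to 0.642 for LEA1 and from 0.000554 to 0.890 for Glc1.

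By their brightest probe sets, the remaining genes with the largest shared changes did not pass the limma test. XIP-I, a xylanase inhibitor protein, was 2.36-fold higher on the PEG array in Luohan No.2 and 2.68-fold in Chinese Spring, with an adjusted p of 0.199 in limma. TaTPC1, a calcium-permeable channel of the vacuole membrane, was 1.93-fold and 1.53-fold higher in Luohan No.2 and Chinese Spring. The peroxidase PER1 was 1.37-fold and 2.57-fold higher, but its other probe set had a log2 change of -0.82 in Luohan No.2. The catalase CAT1 was at least 1.33-fold and 2.19-fold higher at signals of at most 23.2 by its brightest probe set, while the other was above the floor only on the Chinese Spring PEG array, at 25.2. FBP, lgul and SAHH completed the 10, with log2 differences of at least 0.97, at least 0.58 and 0.24 in Luohan No.2 and 0.95, 0.46 and 0.38 in Chinese Spring. The other FBP probe set, near background, was at least 1.16-fold lower in Luohan No.2. Among genes lower in PEG, PsbO, a protein of the oxygen-evolving complex, was 2.86-fold lower in Luohan No.2 and 1.86-fold lower in Chinese Spring, and the zinc finger gene WZF1 was 2.00-fold and 1.84-fold lower. Hmgb3, a high mobility group chromatin protein, was 2.49-fold and 1.36-fold lower by its brightest probe set and 1.28-fold and 1.11-fold lower by the other. By their brightest probe sets, PsbP and petC, likewise of the photosynthetic apparatus, were 1.94-fold and 2.23-fold lower in Chinese Spring and reached the floor on the Luohan No.2 PEG array. The other PsbP probe set had a log2 change of 0.04 in Luohan No.2 and -0.74 in Chinese Spring. The translation factors eIF4E and TEF1, the transcription factor TBP1, and APT1 had differences between -0.14 and -0.73 on the log2 scale in both cultivars, and CL9 was at least 1.16-fold lower in Luohan No.2 and 1.32-fold lower in Chinese Spring. By its brightest probe set, no named gene that was lower in PEG passed the limma test. A second probe set of the tubulin gene TUBA did, at signals of 914.5 in water and 32.9 in PEG in Luohan No.2 (27.8-fold lower) and 997.2 and 447.9 in Chinese Spring (2.23-fold lower), with a limma adjusted p of 0.0462, and it was noticed only after its values were seen. The brighter TUBA probe set, whose name marks possible cross-hybridisation, had log2 changes of -0.03 and -0.06. The 5' to 3' signal ratio of the sucrose synthase control, given below, was lowest on the Luohan No.2 PEG array. The size of the TUBA fall there may therefore depend on the position of the probes in the transcript, which was not tested.

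Over both cultivars 366 probe sets rose and 279 fell with PEG at the limma threshold, and all 645 were at least 2-fold apart in each cultivar in the same direction. This agreement is largely built into the fit, whose residual is the difference between the cultivars' responses, and is no separate support for the calls. At an unadjusted p under 0.05 in limma there were 4640 probe sets, where evenly spread p-values would give 2444 of the 48877 tested. The fit sets changes mainly against a pooled spread, while noise differs with signal level. The excess over 2444 is therefore not a count beyond chance. An informative gene name was paired with 6 of the 645, which were 3 probe sets of Rab15 and 1 each of LEA1, Glc1 and TUBA. Among the unnamed probe sets, Ta.13255.1.S1_at was at least 112-fold higher in Luohan No.2 and at least 408-fold higher in Chinese Spring, and Ta.14931.1.S1_at was at least 80.3-fold higher in Luohan No.2 and 81.9-fold higher in Chinese Spring (limma adjusted p = 3.14e-05 for each). Ta.8319.1.A1_at was 33.6-fold lower in each cultivar (limma adjusted p = 9.65e-05), and Ta.4747.2.S1_x_at was 17.5-fold and 23.1-fold lower (limma adjusted p = 0.000261). The number of calls depended on the fit: limma without the cultivar block, with the floor at the 20th or 60th percentile, or with the floor at 100 called 0 probe sets, against 2896, 4226, 3131 and 1786 at an unadjusted p under 0.05. With any single array left out of the fit without the block it also called 0, with between 3909 and 7370 at that unadjusted p.

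Within Luohan No.2, 2944 probe sets were at least 2-fold higher in PEG and 3869 were at least 2-fold lower, of 38468 measured. In Chinese Spring the numbers were 4560 higher and 4890 lower of 46102. Of 35693 probe sets measured in both, 905 were higher in both cultivars, where independent lists would share 285, and 874 were lower in both, where they would share 402. Opposite moves were fewer than independent lists would give: 156 were higher in Luohan No.2 and lower in Chinese Spring (302 for independent lists), and 269 the reverse (379). The log2 changes of the cultivars correlated at r = 0.33 (Spearman 0.19) across probe sets, which are not independent replicates.

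Gene groups were assembled after the values had been seen, so their percentiles only describe these arrays. Of 5 late embryogenesis abundant and related seed-type proteins, 3 were at least 2-fold higher in PEG in Chinese Spring by their brightest probe sets: Rab15, LEA1 and, at a signal of 27.0, EMH2. The other EMH2 probe sets did not settle a 2-fold rise there, with a log2 change of at least 0.89 and with signals below the floor. COR410 and EM had log2 differences of -0.14 and 0.05 there. The group median in Chinese Spring, the value of EMH2, was 1.28 on the log2 scale, at the 99.7th percentile of random lists, and ranged from 0.79 with the pseudocount to 6.37 with the floor at the 60th percentile. By their brightest probe sets, Rab15 and LEA1 were the 2 members above the floor in Luohan No.2. By their brightest probe sets, 0 of 7 tubulin and profilin genes passed 2-fold in either cultivar, with median log2 changes of 0.07 in Luohan No.2 and -0.10 in Chinese Spring, the latter 0.00 after quantile normalization, although the other TUBA probe set passed in both. By the same measure the 5 core histone genes stayed within 2-fold, with medians of 0.27 and -0.08, although a second H2A-3 probe set had 1.06 in Luohan No.2, and so did the 5 translation initiation and elongation factors, with medians of -0.30 and -0.14.

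**Figure D1:**
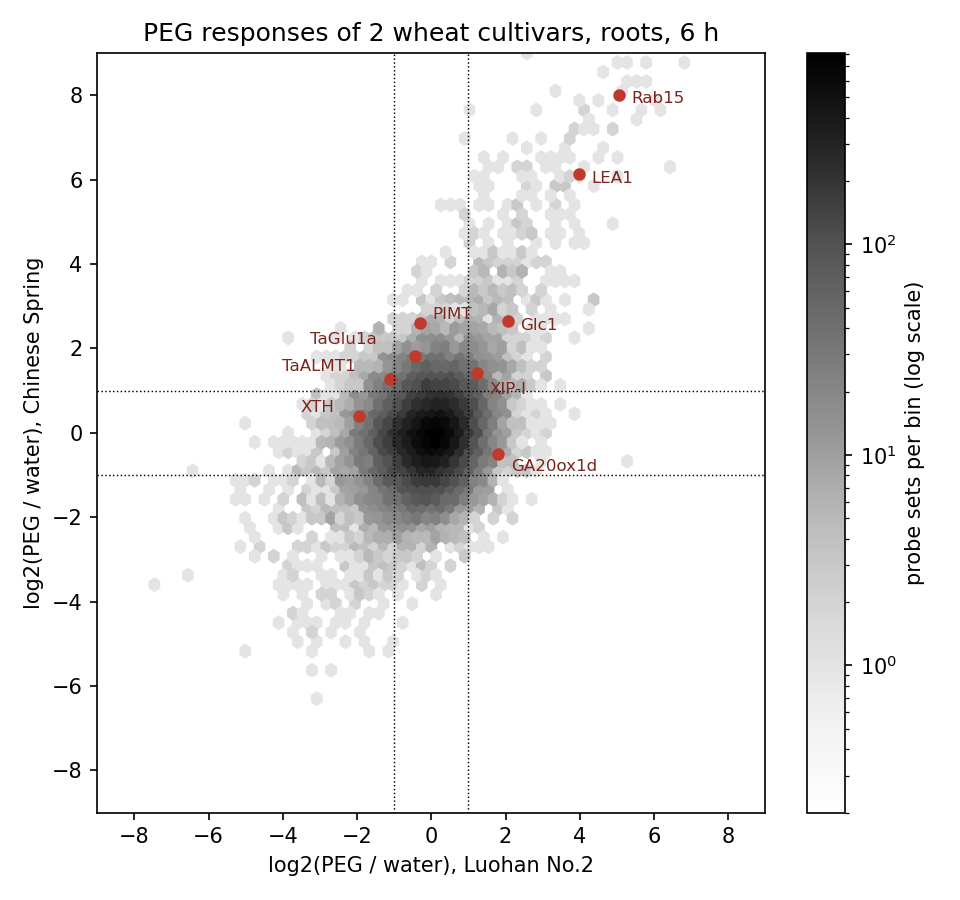
Log2 ratio of PEG to water for each probe set in Luohan No.2 (horizontal axis) against Chinese Spring (vertical axis); shading gives the number of probe sets per hexagon on a log scale, signals below the floor of 10.6 were set to it, dotted lines mark 2-fold, and red points are named genes. Rab15 and LEA1 lie at the upper right, at 5.05 and at least 8.01 for Rab15 and at 3.98 and 6.12 for LEA1.

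Where both cultivars had higher signals in PEG, the difference from water was larger in Chinese Spring. The 905 probe sets higher in both had a median log2 change of 1.52 in Luohan No.2 and 1.88 in Chinese Spring, with a median difference of -0.34 (95% bootstrap interval over probe sets -0.45 to -0.28). The 874 lower in both had medians of -1.54 and -1.62, with a median difference of 0.02 (-0.03 to 0.06). Among those above the floor on all 4 arrays, the differences were -0.27 (-0.34 to -0.19) for 571 higher and -0.01 (-0.06 to 0.05) for 595 lower. Among those above 100 on an array, they were -0.70 (-0.81 to -0.53) for 600 higher and -0.01 (-0.08 to 0.05) for 506 lower. A probe set that rose could pass 100 through a single PEG array, so the 600 were partly chosen on the values compared. These intervals treat probe sets as independent and do not include variation between plants. The 5' to 3' signal ratio of the sucrose synthase control, a measure of how complete the labelled transcripts were, was 0.0554 and 0.0216 on the Luohan No.2 water and PEG arrays and 0.0805 and 0.0693 on the Chinese Spring water and PEG arrays.

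Several named genes had unequal responses, and none of these differences could be tested with 1 array per group. The Luohan No.2 PEG array had the lowest 5' to 3' ratios of the sucrose synthase, glucose-6-phosphate dehydrogenase and ubiquitin controls (0.0216, 0.243 and 1.59). On its water array they were 0.0554, 0.375 and 2.45. Lower signals on that PEG array may therefore depend on the position of the probes in the transcript, which was not tested for these genes. PIMT, a protein-repair methyltransferase, was 6.03-fold higher in PEG in Chinese Spring and 1.23-fold lower in Luohan No.2. The beta-glucosidase gene TaGlu1a was 3.52-fold higher in Chinese Spring and 1.37-fold lower in Luohan No.2. XTH, a xyloglucan-modifying enzyme of the cell wall, was 3.87-fold lower in Luohan No.2 and 1.31-fold higher in Chinese Spring. TaALMT1, a malate transporter known from aluminium tolerance, was at least 2.16-fold lower in Luohan No.2 and 2.42-fold higher in Chinese Spring. Rab15 completed the 5 genes with the more positive change in Chinese Spring. PEAMT1, a methyltransferase of choline synthesis outside the naming rule and picked after its values were seen, was 4.08-fold higher in Chinese Spring and 1.09-fold higher in Luohan No.2.

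The gibberellin 20-oxidase GA20ox1d, an enzyme late in gibberellin synthesis, was 3.50-fold higher in PEG in Luohan No.2 and at least 1.42-fold lower in Chinese Spring. GA20ox1a was 1.61-fold higher and at least 2.02-fold lower, respectively. Signals of the 3 GA20ox1 genes were at most 52.8, and such homoeologues can share probes. The thionins THI1.2 and THI1.1, small antimicrobial proteins, had log2 changes of 0.49 and 0.22 in Luohan No.2 and -0.83 and -0.97 in Chinese Spring, where the other THI1.1 probe set had -0.35. The gene listed as at2G04570 had at least 0.37 and -0.89. Over 35693 probe sets, the responses differed at least 4-fold for 820 with the more positive change in Luohan No.2 and 1288 with the more positive change in Chinese Spring. With the floor at 100 these counts were 107 and 195.

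**Figure D2:**
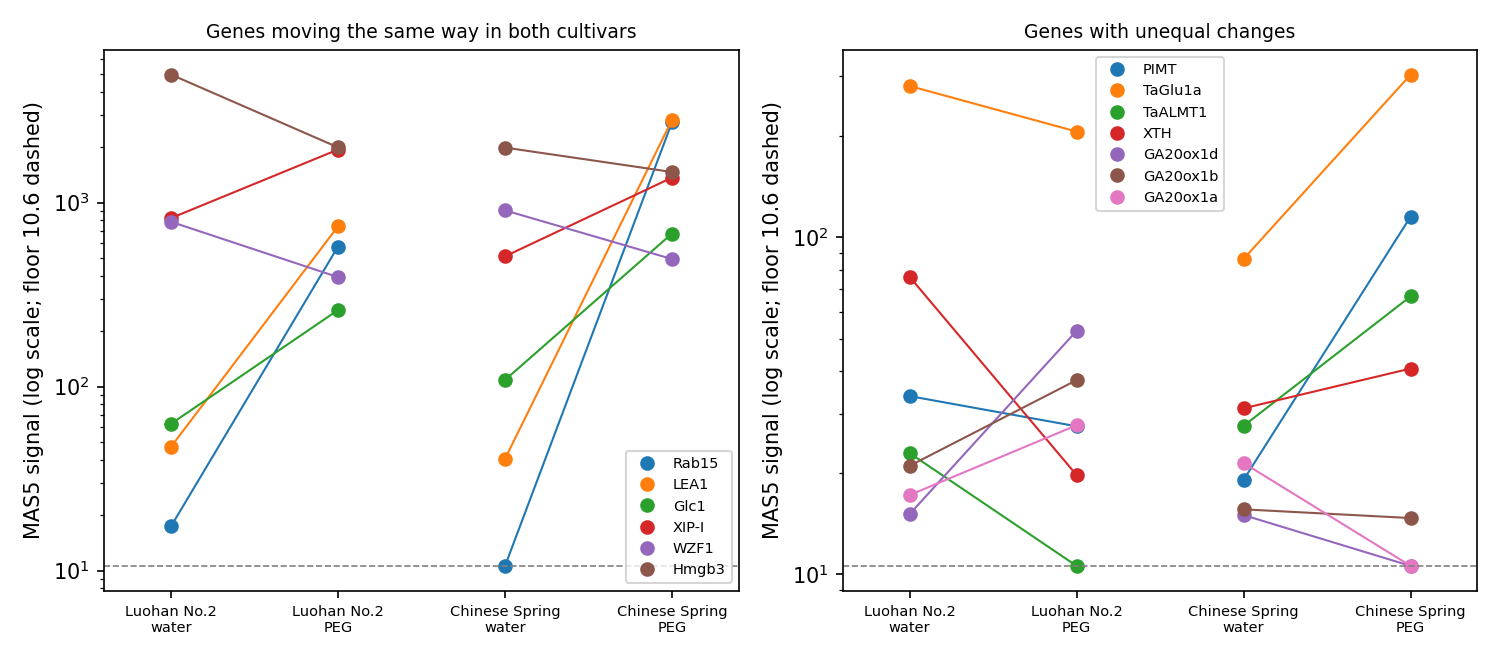
MAS5 signal (log axis) of named genes on each of the 4 arrays, 1 point per array, lines joining water and PEG within a cultivar, values below the floor of 10.6 (dashed) drawn at it. The left panel holds genes that moved the same way in both cultivars, such as XIP-I at 824.1 and 1943.3 in Luohan No.2 and 510.7 and 1368.2 in Chinese Spring; the right panel holds genes with unequal changes, such as PIMT at 33.8, 27.5, 19.1 and 115.2 from left to right.

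Genes of photosynthesis separated the cultivars in both conditions, in roots. All 7 members of this group, assembled after the values had been seen, were at least 2-fold higher in Chinese Spring in water and again in PEG by their brightest probe sets. The median log2 differences of Luohan No.2 from Chinese Spring were -2.54 (0.035th percentile of random lists) and, with Trx-M at the floor, -1.73 or lower (0.58th percentile). Other probe sets did not all go this way. The other FBP probe set, near background, had signals of 12.3 in Luohan No.2 and 2.7 in Chinese Spring in water. In PEG a further rbcl probe set had 60.3 in Luohan No.2 and 11.2 in Chinese Spring, while another had 2837.7 and 7464.6. The gene petC, for the Rieske protein of the cytochrome b6f complex, was 21.7-fold higher in Chinese Spring in water and at least 12.2-fold in PEG, with a limma adjusted p of 0.000206. By its brightest probe set PsbP was 5.80-fold and at least 5.25-fold higher in Chinese Spring (limma adjusted p = 0.00568). The other PsbP probe set did not pass, with signals of 15.6 and 16.0 in Luohan No.2 and 62.0 and 37.1 in Chinese Spring (limma adjusted p = 0.0801). The Calvin cycle kinase PRK and the plastid thioredoxin Trx-M, both at the floor on the Luohan No.2 arrays, were at least 7.02-fold and 6.48-fold higher in water (limma adjusted p = 0.0208 and 0.0168), and PsbO was 2.76-fold higher in water and 4.24-fold higher in PEG (0.0490). The large Rubisco subunit gene rbcl had signals of 2880.2 and 2678.3 on the Luohan No.2 arrays and 8007.0 and 7764.6 on the Chinese Spring arrays, and its limma adjusted p was 0.0890. Without probe sets marked for cross-hybridisation the rbcl difference in water was -0.34 on the log2 scale. These calls depended on the floor as well: over the alternative floors, scalings and probe set filters the limma adjusted p ranged from 8.06e-08 to 0.478 for petC, from 0.000347 to 0.974 for PsbP, from 0.00373 to 0.506 for PRK, from 0.00369 to 0.464 for Trx-M and from 0.0642 to 0.828 for PsbO. With the floor at the 60th percentile the limma adjusted p was 0.0625 for petC, and its log2 differences were -3.37 in water and -2.21 in PEG. The group medians at that floor were -1.47 and -0.997, and 6 of 6 measured genes in water and 3 of 7 in PEG were at least 2-fold higher in Chinese Spring. With PEG the group's median change was -0.95 in Chinese Spring, at the 1.75th percentile, and, with petC at the floor, -0.33 or lower over 5 measured genes in Luohan No.2, at the 21.5th percentile. By their brightest probe sets, 6 members changed by less than 0 in Chinese Spring and 4 in Luohan No.2. FBP rose in both, by at least 0.97 on the log2 scale in Luohan No.2 and 0.95 in Chinese Spring.

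By probe set signal, other named genes differed between the cultivars in both conditions. Sequence variants that alter hybridisation enter such differences, so they need not reflect transcript abundance. CL9 was 5.23-fold higher in Chinese Spring in water and at least 4.60-fold in PEG (limma adjusted p = 0.00941, and between 0.00283 and 0.348 in the alternatives). The amylase inhibitor WMAI-1 was at least 2.85-fold and 3.08-fold higher there, at signals of at most 32.6 (limma adjusted p = 0.0763). In the other direction, PR5, a thaumatin-like defence protein, was 2.36-fold higher in Luohan No.2 in water and 4.53-fold higher in PEG, with a limma adjusted p of 0.0652. XIP-I was 1.61-fold and 1.42-fold higher in Luohan No.2, eIF4E 1.50-fold and 1.52-fold, Hmgb3 2.49-fold and 1.36-fold, and GA20ox1b 1.35-fold and 2.56-fold. The histone gene wcH2B-8 and APT1 were 1.29-fold and 1.36-fold higher in water, and the lectin gene WGA2 was at least 1.74-fold higher. By their brightest probe sets, these 8 genes higher in Luohan No.2 did not pass the limma test. The other Hmgb3 probe set did, with signals of 2178.9 and 1697.6 in Luohan No.2 and 263.5 and 238.0 in Chinese Spring (limma adjusted p = 0.00155). The wcH2B-8 probe sets differed in direction. One was lower in Luohan No.2, with 72.2 and 48.4 against 253.9 and 265.6 (limma adjusted p = 0.0175). In water others were lower there as well, with 589.8 against 812.7, 459.6 against 568.8 and 421.9 against 474.7. Besides the brightest, those with 552.0 against 406.7 and 229.2 against 203.8 in water were higher.

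In water 2630 probe sets were at least 2-fold higher and 6477 at least 2-fold lower in Luohan No.2 than in Chinese Spring, of 42716 measured, so that 71.1% of the differences were lower. In PEG 2947 were higher and 7062 lower of 43378, or 70.6% lower. This split moved with the scaling and the floor: lower shares were 49.2% in water and 50.8% in PEG after quantile normalization, 56.7% and 59.4% with the floor at the 60th percentile, and 44.8% and 49.6% with the floor at 100. It stayed between 65.4% and 75.3% with the floor at the 20th percentile, the pseudocount, median centring and omission of probe sets marked for cross-hybridisation. The median log2 difference over probe sets above the floor on both water arrays was -0.14, and -0.02 after quantile normalization. In both conditions, 788 probe sets were higher and 1850 lower in Luohan No.2. The limma fit called 395 probe sets higher and 610 lower in Luohan No.2, with 6387 at an unadjusted p under 0.05. Without the condition block limma called 0, with 5259 at that unadjusted p, and with the floor at the 20th percentile 0, with 6044. The 5' to 3' signal ratios of bacterial transcripts spiked into the labelling were lower on the Luohan No.2 arrays: for dap they were 0.0760 and 0.0598 in water and PEG, against 0.372 and 0.320 on the Chinese Spring arrays.

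**Figure D3:**
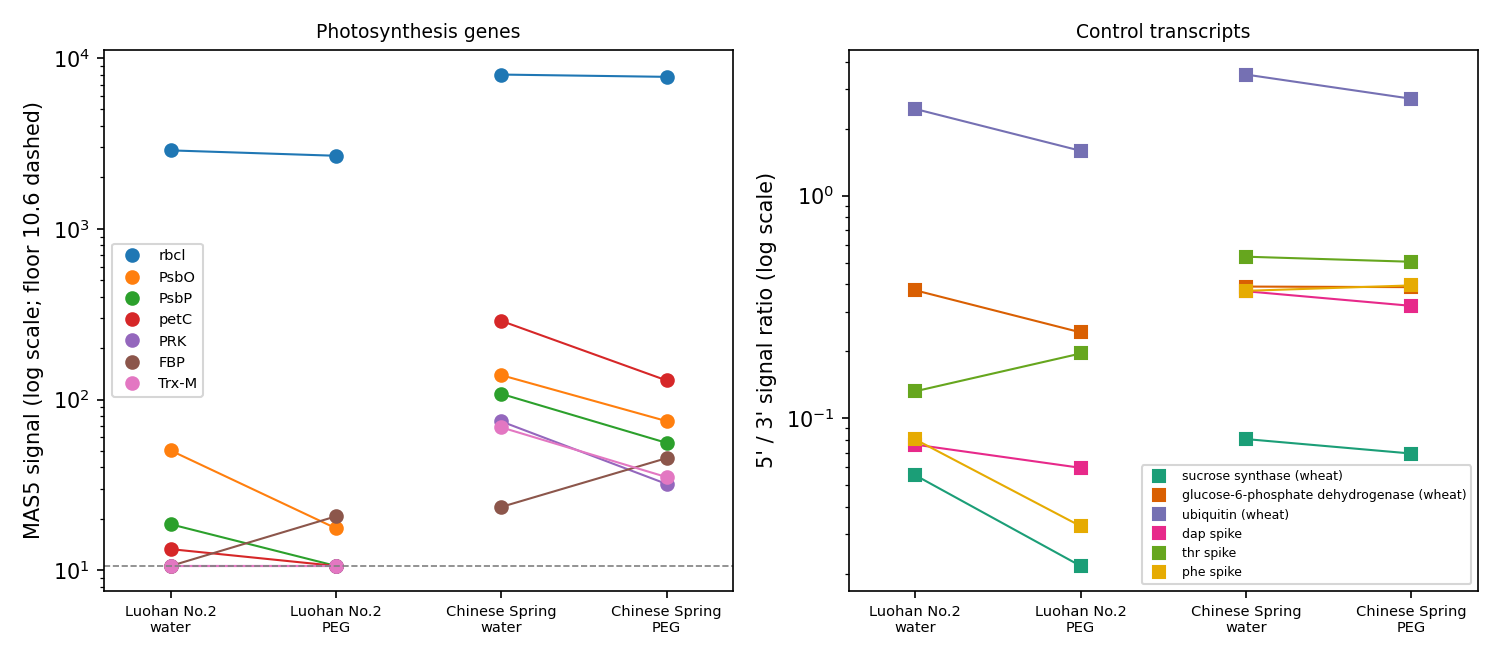
Left, MAS5 signal (log axis) of 7 photosynthesis genes on the 4 arrays, values below the floor of 10.6 (dashed) drawn at it. Right, ratio of 5' to 3' probe set signals (log axis) of wheat and spiked-in bacterial control transcripts on the same arrays; points are single arrays and lines join water and PEG within a cultivar. The dap ratio was 0.0760 and 0.0598 on the Luohan No.2 arrays and 0.372 and 0.320 on the Chinese Spring arrays.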

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

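Apart from quantile normalization and the omission of probe sets marked for cross-hybridisation, the tests in this part were chosen after the values had been seen. TaALMT1 moved in opposite directions, down by at least 1.11 on the log2 scale in Luohan No.2 and up by 1.28 in Chinese Spring, a difference of -2.39 or lower that was not tested. GA20ox1a moved the other way round, by 0.69 in Luohan No.2 and at least -1.01 in Chinese Spring, a difference of 1.70 or more that was not tested either. The signals of TaALMT1 were at most 66.8 and those of GA20ox1a at most 27.7.

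Probe sets higher with PEG in both cultivars differed less from water in Luohan No.2. A response smaller in both directions, taken alone, would have given the probe sets lower in both a clearly positive difference of Luohan No.2 from Chinese Spring. The upper 95% bound of that difference was 0.048 among 595 of them above the floor on all 4 arrays. This bound comes from probe sets chosen at 2-fold in these data and holds no array error. A smaller response together with a shift between arrays was therefore not excluded. Water signals at the floor may account for a part of the gap, which was -0.34 over all 905 probe sets higher in both. Among the 571 of them above the floor on all 4 arrays a gap of -0.27 remained (95% interval -0.34 to -0.19). These too were chosen at 2-fold in these data, and the interval holds no array error. Unequal loss of signal between transcripts, for instance those probed far from their 3' end, stays open, since the sucrose synthase ratio was lowest on the Luohan No.2 PEG array, as does a cultivar difference in the induced genes, for which no test was possible.

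Most 2-fold differences between the cultivars were lower in Luohan No.2. The unequal low-signal range of the arrays is a candidate explanation: with the floor at 100, the larger of the shares that were lower in Luohan No.2 was 49.6%, that under PEG. The labelling reaction may also contribute, since the dap ratio was 4.89 times higher on the Chinese Spring water array than on the Luohan No.2 water array, but labelling and cultivar cannot be told apart because the dap ratios of both Luohan No.2 arrays lay below those of both Chinese Spring arrays. A wider set of active genes in Chinese Spring was not tested, nor were sequence variants between the cultivars that alter hybridisation.

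Photosynthesis genes were higher on the Chinese Spring arrays. The unequal low-signal range may contribute: with the floor at 100 the medians were -0.97 over 4 measured genes in water and -0.95 over 2 in PEG, where the higher floor shrinks differences by construction. Quantile normalization, which evened the split of the cultivar differences, left medians of -2.21 and -1.62 with 6 of 7 genes at least 2-fold higher in Chinese Spring in each condition, which speaks against it, but a group put together after its values were seen does not exclude it. By their brightest probe sets, 7 of 7 genes were at least 2-fold higher in Chinese Spring in both conditions. Green tissue in the Chinese Spring samples could give this, and so could plastid transcripts of the root itself in that cultivar. These cannot be told apart without a marker of shoot tissue that roots lack. Without probe sets marked for cross-hybridisation the count was 5 of 6 in water, where rbcl differed by -0.34 on the log2 scale, and 6 of 6 in PEG. The labelling reaction stays open for this group as well and cannot be told apart from cultivar. The dap ratios were 0.0760 and 0.0598 on the Luohan No.2 arrays and 0.372 and 0.320 on the Chinese Spring arrays. Sequence variants that alter hybridisation were not tested.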

How the results depend on the processing

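Alternatives with the floor at 100 and the groups of genes were chosen after seeing the data. Of 990 values for named genes and the smaller groups under the alternatives, 908 moved by less than the spread between probe sets of a cluster, 81 moved by more, and 1 reversed from a size of at least 1 on the log2 scale, the Glc1 difference between cultivars in PEG, which was 0.36 without probe sets marked for cross-hybridisation because another probe set then stood for the gene. Of the other results, 83 stayed within 1.5 times or within that spread and 98 did not. Directions held, in all alternatives that gave a value, for the photosynthesis medians between cultivars and with PEG and for the late embryogenesis medians with PEG. Between 54.8% and 64.9% of probe sets were above the floor on an array, and counts near background move with it. Except where stated, the cause of a change was not tested.

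With the floor at the 20th percentile, PEG responses in Luohan No.2 gave 8958 higher and 9019 lower, in Chinese Spring 10678 and 10317, shared 2579 and 2219 with r = 0.16; cultivar differences were 7188 higher and 13931 lower in water and 7608 and 14400 in PEG; responses differed 4-fold for 4605 and 5045; the late embryogenesis median in Luohan No.2 was 1.64. With the floor at the 60th percentile the same counts were 1547 and 2294, 1777 and 1976, 561 and 499, 1577 and 2067, 1828 and 2670, and 257 and 588; the late embryogenesis median in Chinese Spring was 6.37 and the photosynthesis medians were -1.47 in water and -0.997 in PEG. With the floor at 100 they were 822 and 1099, 948 and 851, 313 and 278, 788 and 639, 1005 and 990, and 107 and 195, with late embryogenesis medians of 2.71 and 4.80 and photosynthesis medians of -0.97 and -0.95. These counts move by construction, since the floor sets which probe sets can differ. At a 3-fold threshold the PEG responses were 800 and 1274 in Luohan No.2, 1532 and 1444 in Chinese Spring, and 325 and 268 shared. The pseudocount gave a photosynthesis median of -2.02 in water. Quantile normalization gave 3618 lower in water and 4431 lower in PEG in Luohan No.2, and late embryogenesis medians of 3.86 and 3.72; without probe sets marked for cross-hybridisation that median was 3.96 in Luohan No.2.

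Every setting in which limma's prior was below 6 degrees of freedom called fewer probe sets than the 366 and 279 for PEG and 395 and 610 for cultivar. The prior was 11.63 as reported, 3.99 and 4.41 with the floors at the 20th and 60th percentiles, 4.17 at 100, 5.75 after quantile normalization and 2.20 without the cultivar block. PEG calls (higher, lower) were 0 and 0 with the floors at the 20th percentile, 60th percentile and 100 and without the block, against 4226, 3131, 1786 and 2896 at an unadjusted p under 0.05. They were 34 and 20 after quantile normalization, 684 and 643 with the intensity trend, 461 lower with the pseudocount and 160 lower without probe sets marked for cross-hybridisation. Cultivar calls were 0 and 0 in limma with the floor at the 20th percentile (6044 at an unadjusted p under 0.05) and without the block (5259), 112 and 102 at the 60th percentile, 30 and 22 at 100, 225 and 187 after quantile normalization, and 646 higher with the trend. With each array left out in turn of the limma fit without the block, PEG and cultivar calls ranged from 0 to 0, with 3909 to 7370 and 3955 to 10954 probe sets at an unadjusted p under 0.05; the condition left with 1 array is assumed to vary like the other. No paired analysis by replicate number was possible because each group holds 1 array.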

Other observations

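The sucrose synthase control probe sets, which also report the wheat transcript of this sucrose-cleaving enzyme, were lower in PEG. The 3' probe set was 1.89-fold lower in Luohan No.2 (5639.4 and 2988.6) and 1.50-fold lower in Chinese Spring (7736.0 and 5169.1), the middle probe set 4.46-fold and 1.77-fold lower, and the 5' probe set 4.83-fold and 1.74-fold lower. The 5' to 3' ratio on the Luohan No.2 PEG array was 0.0216, against 0.0554 on its water array, so the size of the difference there depends on the position in the transcript. The 3' probe set of CYP86, a cytochrome P450 family whose members oxidise fatty acids, was 2.21-fold higher in PEG in Luohan No.2 (49.6 and 109.4) and 2.99-fold higher in Chinese Spring (54.4 and 162.7). The 3' probe sets of ubiquitin and glucose-6-phosphate dehydrogenase had log2 changes of 0.26 and 0.02 in Luohan No.2 and 0.39 and 0.69 in Chinese Spring. Control probe sets were not among those tested with limma.

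Grain proteins and inhibitors, a group of 21 genes assembled after the values had been seen, were mostly near the floor in roots. In Luohan No.2, 6 were measured in the PEG comparison and 0 passed 2-fold. In Chinese Spring 16 were measured, of which 2 were at least 2-fold higher and 1 at least 2-fold lower in PEG. In water, 7 of 12 measured members were at least 2-fold lower in Luohan No.2. The median log2 difference, with ATI and WSZ1b at the floor in Luohan No.2, was -1.12 or lower (percentile 0 among random lists). In PEG 4 of 13 were, with a median, that of avnla at the floor in Luohan No.2, of -0.62 or lower (28.7th percentile). Members at the floor in Luohan No.2 were measured through the Chinese Spring array alone, so the unequal low-signal range could contribute. The small heat shock gene hsp16.9A had a signal of 28.3 in PEG and 6.5 in water in Luohan No.2 and stayed below the floor in Chinese Spring, and LTP3, a lipid transfer protein, reached 23.3 on the Chinese Spring PEG array alone. Both were picked after their values were seen.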
